A study of Mus musculus with 12 samples.

How the data were processed

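The starting values were the scanner files of 12 single-colour Agilent mouse arrays, each with 62976 spots, of which 59305 were not controls and held 55681 probes. The processed spot intensity was made by the authors with Agilent Feature Extraction 10.7, per the submitters' processing notes. Per the file headers these intensity values had spatial and multiplicative trends removed and surrogates set for dim spots, with the separate background correction switched off. The deposited value table holds log2 values that the authors shifted so that the 75th percentile of each array is 0, and its 55821 entries per array matched the scanner values on that scale. It was used only as an alternative. In it the columns of the array labelled survivin-deleted liver replicate 1 and of the array labelled wild-type HCC replicate 1 match each other's scanner file (r = 0.963 with the own file, 1.00 with the other's), and the assignment recorded for the scanner files was used throughout unless said otherwise.

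Groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Processed signals were put on the log2 scale, unflagged spots of a probe were averaged, and the 75th percentile of each array was subtracted. For 636 probes every spot was flagged on an array. A probe was kept if it was well above background on all arrays of at least 1 group, which left 38714 probes, and the probe of highest mean stood for each gene, which gave 26290 genes, 11364 of them with clone-like names. Of these genes 7729 had more than 1 probe. The files give 34844 gene names on the mm9 assembly. Accessions of 26762 probes were matched to a later gene reference for current symbols only, which changed 2878 symbols, and where a symbol changed the text gives both. No saturated spots were found, with 0 on every array.

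The limma model had 4 group means over all 12 arrays with 8 residual degrees of freedom, moderated variances and Benjamini-Hochberg adjustment at 0.05 in each of 5 contrasts. These were survivin deletion in HCC, survivin deletion in non-cancerous liver, HCC against liver in each genotype, and the difference between the deletion changes of the tissues. For 36 gene lists with 713 of 760 entries measured, limma camera was run with a preset correlation of 0.01 and adjusted over the lists of a contrast, beside camera with the correlation estimated per list and the rotation test fry. Birc5 was also tested by exact permutation of 3 against 3 arrays. The lists covered mitosis, the chromosomal passenger complex, replication, DNA damage repair, apoptosis, p53, liver metabolism, stress responses, acute-phase proteins, and markers of liver, blood, immune, cholangiocyte, pancreatic acinar and adipose cells.

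Genes are named by a fixed rule. Birc5 is always named, then up to 10 of the largest changes per direction among genes past the adjusted threshold with separated groups. Where fewer pass, the genes of smallest unadjusted p are added up to 5 per direction and said not to have passed. From each called list up to 4 members of smallest p in the direction of the list may be named, of which the text gives a selection. Clone-like names are left out, and 1 gene that the rule names is not reported here. The genes that passed only in alternative fits, and the Y-linked and zonation genes, were named after their values were seen. XIST falls under the rule in HCC, and its other probes were read after seeing that value.

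Slide was read from the array identifiers. Replicate numbers 1 to 3 in the titles pair arrays through the slide. Over 18 comparisons of same-numbered arrays the correlations of deviations from the group means were 0.279 to 0.737, and 14 were above every correlation with another number. Within slide 2 they were -0.0913 to 0.285, with 2 of 6 over 0.1. Fits with slide as a block had 7 residual degrees of freedom.

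Alternatives were quantile normalization, normexp background correction with an offset of 50 followed by quantile or 75th percentile scaling, no filter, a filter on all arrays, the mean of all probes of a gene, slide as a block, the replicate number as a block, slide 2 only, only the groups compared, trended robust variances, array weights, the value table, a size threshold and leaving out each array in turn. Chosen after seeing the data were the fits with the 2 arrays exchanged, with the same and a slide block, and without both arrays in doubt with a slide block.

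The fit was tried on simulated changes added to the arrays of the HCC contrast in 26290 genes. First the random spread included the slide differences and no slide effect was added. There the fit without a block recovered 3.03%, 27.5% and 61.5% of genes changed 2-fold, 4-fold and 8-fold. Then the spread was free of slide and a slide effect was added to each gene. There the same fit recovered 0%, 21.7% and 64.6%, and the slide-blocked fit 28.8%, 73.9% and 84.6%. False calls were 2, 1 and 6 genes in this order. Camera called the shifted list of 20 members and 0 of the others. The simulated genes varied independently of each other, so this does not test list calls where members are correlated. Versions were R 4.3.3, limma 3.58.1, data.table (1.17.8), Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.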

Results

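Transcript levels in mouse liver were measured on 12 single-colour Agilent arrays. Male mice of mixed strain had received diethylnitrosamine (DEN), a carcinogen that induces hepatocellular carcinoma (HCC), at 50 mg/kg when 2 weeks old. All were irradiated and given a bone marrow transplant 2 months before the tissue was taken. Deletion of survivin, the product of Birc5, was driven by Mx-Cre, a recombinase that poly(IC) switches on in liver and blood cells, and tissue was taken 1 week after poly(IC). Survivin acts in the chromosomal passenger complex during mitosis and also limits apoptosis. The design crossed tissue with genotype in 4 groups of 3 arrays, which were wild-type liver, survivin-deleted liver, wild-type HCC and survivin-deleted HCC, where liver stands for the non-cancerous tissue. The labels do not say whether arrays of a group came from separate animals. Nor do they say whether tumour and liver of the same genotype and replicate number came from the same animal. The tissue contrasts treat such arrays as independent. The limma, exact and fry p-values thus measure only the spread between these samples. Camera p-values with the preset correlation compare the members of a list with all other genes. The correlation between genes is fixed there rather than taken from the samples. The 75th percentile of the signal lay between 1283 and 1958 on the 4 arrays of slide 1 and between 3639 and 4243 on the 8 arrays of slide 2. The share of spots well above background was 49.0% on wild-type liver replicate 1 and 69.2% to 83.4% on the others. Slide 1 held replicate 1 of each group and slide 2 held replicates 2 and 3, and the first principal component, with 53.2% of the variance, separated the slides. The number of arrays limits the precision of every value below.

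The target gene itself was read first. The Birc5 probe of highest signal (mm9 chromosome 11, 117716978 to 117717037) averaged 0.05 ± 0.13 in survivin-deleted HCC and 1.12 ± 0.55 in wild-type HCC (log2 relative to the array's 75th percentile, SD, n = 3). The difference was -1.08 (SE 0.83) or 2.11-fold lower, and the arrays of the groups did not overlap (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 arrays allow). In non-cancerous liver the means were 0.42 ± 1.80 with deletion and 1.37 ± 1.29 in wild type (SD, n = 3), a difference of -0.96 (exact permutation test, two-sided, p = 0.5). The limma test gave unadjusted p = 0.219 in HCC and 0.271 in liver. A second probe (chromosome 11, 117711112 to 117711171) was lower by -1.79 in HCC and by -1.24 in liver, and another (117714057 to 117714116) by -1.09 and -0.98. By limma the unadjusted p of the second probe was 0.0302 in HCC and 0.112 in liver. That of the other was 0.0932 and 0.127. Its HCC groups overlapped (exact permutation test, two-sided, p = 0.2), and on slide 1 it was 0.33 higher in deleted HCC. The array labelled survivin-deleted liver replicate 1 went against its label. Its Birc5 signal was 2.42 on the probe of highest signal, where replicates 2 and 3 had -0.10 and -1.07 and wild-type liver on the same slide had 2.85. On the probe at 117711112 it read -0.33, against -2.54 and -3.33 in the other 2 deleted livers. On that probe the array labelled wild-type HCC replicate 1 read -2.03, against -0.85 and 0.09 in replicates 2 and 3.

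The deposited value table held the signals of the array labelled survivin-deleted liver replicate 1 under the name of wild-type HCC replicate 1, and the reverse (r = 0.963 with the own scanner file and 1.00 with the other, across 55681 probes). The scanner assignment was kept for the values below. With these 2 arrays exchanged, a choice made after seeing the data, the Birc5 differences were -1.62 in HCC and -1.50 in liver (exact permutation test, p = 0.1 and 0.3). By limma their unadjusted p was then 0.0324 and 0.0446, and 0.00445 and 0.00698 with slide as a block. On the probe at 117711112 they were -2.36 and -1.81 (exact p = 0.1 in both tissues, limma unadjusted p = 1.18e-04 and 9.58e-04), and on the probe at 117714057 -1.51 and -1.40 (exact p = 0.1 in both, limma unadjusted p = 0.00136 and 0.00230). On the probe at 117711112 the differences on slide 1 alone were then -2.35 and -1.80, beside -2.36 and -1.81 on slide 2. Within slide 2 the probe of highest signal differed by -1.25 and -1.22 (2 arrays per group, limma unadjusted p = 0.0238 and 0.0259). As labelled, with slide as a block, its unadjusted p-values were 0.147 and 0.192. The labels do not say which part of Birc5 is deleted, so a probe outside that part would not report the deletion.

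**Figure D1:**
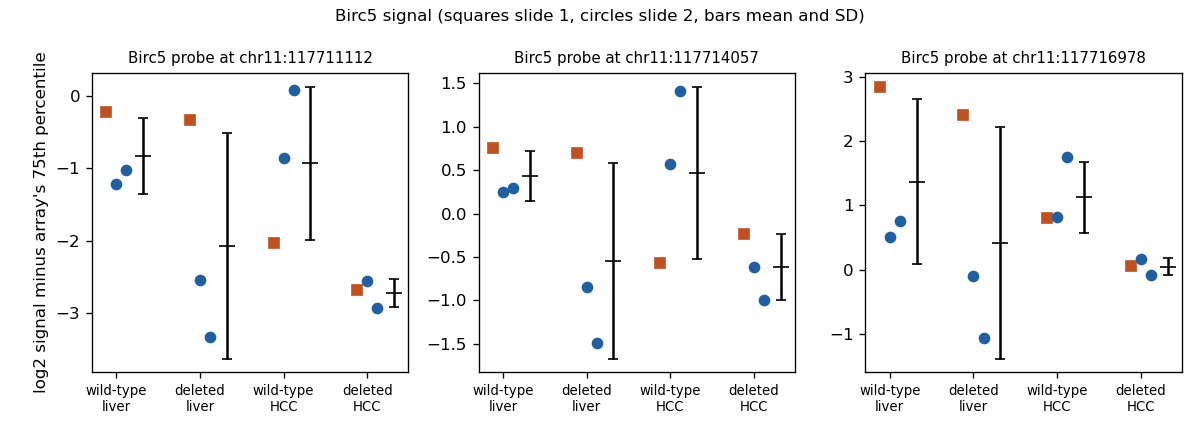
Signal of the 3 Birc5 probes on each array (vertical axis, log2 signal minus the array's 75th percentile), by group (horizontal axis), with squares for slide 1, circles for slide 2 and bars for the mean and SD of 3 arrays. The square of survivin-deleted liver stands beside the square of wild-type liver on all 3 probes, while both circles of survivin-deleted liver lie below those of wild-type liver.

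Survivin-deleted HCC differed from wild-type HCC most in genes that Wnt and beta-catenin signalling activates in hepatocytes. All 18 measured members of this list were higher, with a median log2 change of 2.01 and a mean of 2.01 ± 0.44 (SE with slide as a block, 3 arrays per group). Glul, the glutamine synthetase of pericentral hepatocytes, was 4.33-fold higher (3.09 ± 0.61 against 0.98 ± 0.40, SD, n = 3). Axin2, a feedback inhibitor of the pathway, was higher too, but was above background on 1 of the 3 wild-type arrays, so no size is given. The transcription factor Tbx3 was higher by 2.80 (SE 0.61) and Lect2, a secreted hepatocyte protein, by 1.90 (SE 0.42). The list rose by camera (adjusted p = 7.42e-24), and adjusted p = 0.17 with an estimated correlation. No member passed over all genes tested, 10 did so at unadjusted p under 0.05 and 9 when adjusted over the list alone. In a fit with slide as a block 14 passed adjusted over the list alone (camera adjusted p = 1.14e-17), and within slide 2 13 did, with a median of 2.55. With the 2 arrays exchanged the median was 1.82 (camera adjusted p = 5.08e-13), and 0 members passed adjusted over the list alone. Slide 1 then showed no rise, with a list mean of 2.26 in survivin-deleted HCC against 2.29. The groups of Axin2 and Tbx3 then overlapped, while those of Glul and Lect2 did not.

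Lymphocyte and myeloid transcripts were also higher in survivin-deleted HCC, mainly on slide 2. T and NK cell markers had a median of 1.20, with 16 of 19 members higher, among them Cd3d by 1.75 (SE 0.65) and Cd3g by 1.74 (SE 0.78), both parts of the T-cell receptor complex. This list rose by camera (adjusted p = 3.39e-06), with adjusted p = 0.31 with an estimated correlation. Leaving out 1 array moved its median to between 0.63 and 1.75 (largest adjusted p = 0.00270). Blocked by slide its adjusted p was 2.29e-05, and within slide 2 the median was 1.68. With the 2 arrays exchanged the median was 0.70 (adjusted p = 0.0178), and 0.0828 with the slide block added. Markers of B and plasma cells (median 0.87), macrophages (0.39) and monocytes and neutrophils (0.15) rose too, with adjusted p = 0.00202, 0.00178 and 0.0445, and adjusted p = 0.24, 0.43 and 0.43 with an estimated correlation. Blocked by slide the adjusted p of the monocyte and neutrophil list was 0.104. On slide 1, as labelled, the T and NK cell list mean was -1.14 in deleted and -1.21 in wild-type HCC. The B and plasma cell (-1.82 against -1.59), macrophage (2.36 against 2.44) and monocyte lists (2.06 against 2.51) were lower with deletion there. With the 2 labels exchanged the T and NK cell list was lower there too (-1.14 against 0.06). Among macrophage markers the scavenger receptor gene Msr1 was higher by 1.02 (SE 0.33). Interferon-stimulated genes rose by a median of 0.27 (camera adjusted p = 3.01e-05, and adjusted p = 0.17 with an estimated correlation), with 24 of 33 members higher. The guanylate-binding protein genes Gbp3 (1.42, SE 0.32, adjusted p = 0.0358 over the list alone) and Gbp2 (1.79, SE 0.72) led it. With the 2 arrays exchanged the Gbp3 groups overlapped, at 1.12 on the array filed as survivin-deleted liver and 1.03 in survivin-deleted HCC replicate 3. Genes of antigen presentation were higher in 16 of 16 members (median 0.27, adjusted p = 3.75e-04, and adjusted p = 0.24 with an estimated correlation). Among single genes Cd274, which encodes the T-cell inhibitory ligand PD-L1, was 6.43-fold higher (SE 0.52 on the log2 scale). With the 2 arrays exchanged its groups overlapped. The array filed as survivin-deleted liver read -0.79, above survivin-deleted HCC replicate 3 at -1.32. XIST, described below, parted the same arrays of slide 2 by genotype.

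Several metabolic groups moved with them. Cytochrome P450 genes rose by a median of 0.49 (adjusted p = 2.32e-05, and adjusted p = 0.28 with an estimated correlation), with Cyp1a2 higher by 2.68 (SE 0.99) and Cyp2c38 by 1.27 (SE 0.48). Cyp1a1, a xenobiotic-induced P450, was not well above background on any wild-type HCC array and was at least 3.40-fold higher in deleted HCC. Cyp1a2 and Cyp2e1 were on both this list and the Wnt list. Genes with higher expression in female liver rose by a median of 0.51 (adjusted p = 1.76e-04), among them the sulfotransferase genes Sult3a1 (4.23, SE 1.19) and Sult1e1 (2.34, SE 0.75). Tumour and oncofetal genes (0.51), hypoxia and glycolysis genes (0.42), secreted senescence genes (0.54), NRF2 targets (0.15) and p53 targets (0.16) rose as well. Their camera adjusted p-values were 2.07e-04, 6.76e-04, 0.0177, 0.0194 and 0.0456. The female-biased list had adjusted p = 0.24 with an estimated correlation, and these 5 lists had adjusted p = 0.17, 0.28, 0.43, 0.51 and 0.24. The stress gene Ndrg1 was higher by 1.18 (SE 0.36), Egln3, an oxygen-sensing hydroxylase gene, by 1.82 (SE 0.73), and the p53 target Phlda3 by 1.00 (SE 0.33). With the 2 arrays exchanged the groups of Sult3a1, Ndrg1 and Phlda3 overlapped. Amino acid, urea and gluconeogenesis genes fell by 0.32 in the median, with 22 of 28 lower (adjusted p = 3.99e-04, and adjusted p = 0.43 with an estimated correlation). Without survivin-deleted HCC replicate 2, whose list mean was 3.07 against 4.16 and 4.32 in the other replicates, the median was -0.00752 (adjusted p = 0.638). Without the same array the senescence median was -0.02 (adjusted p = 0.603), its list mean being 0.34 there against -0.21 and -1.32. Genes of fatty acid synthesis fell by 0.19, among which the pyruvate kinase gene Pklr differed by -1.09 (SE 0.42), and genes of cholesterol synthesis fell by 0.26. Mitosis and spindle genes fell by 0.24 and secreted hepatocyte proteins fell by 0.10. Their adjusted p-values in this order were 0.0112, 0.0406, 0.0127 and 0.0459, and adjusted p = 0.17, 0.58, 0.58 and 0.43 with an estimated correlation. In the slide-blocked fit NRF2 targets (adjusted p = 0.0545), cholesterol synthesis (0.0664) and secreted proteins (0.0552) lost the call. Within slide 2 the medians of the mitosis and cholesterol lists were -0.61 and -0.49, while the oncofetal, amino acid, senescence, NRF2, p53 and secreted protein lists did not pass (adjusted p from 0.127 to 0.329). With the 2 arrays exchanged the oncofetal (adjusted p = 0.123), amino acid (0.0560), fatty acid synthesis (0.0679), NRF2 (0.116), p53 (0.211) and secreted protein lists (0.870) did not pass.

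In total 19 of 36 lists passed in this comparison, 14 up and 5 down, with 0 under an estimated correlation and 0 by fry, 15 with slide as a block, 15 within slide 2 and 16 with the 2 arrays exchanged. The Wnt, T and NK cell, P450, interferon, female-biased, antigen presentation and B-cell lists kept their call whichever array was left out, and every other list lost it without at least 1 array. Leaving out 1 array moved the P450 median to between 0.35 and 0.90 and the antigen presentation median to between 0.22 and 0.58. The B and plasma cell median moved to between 0.37 and 1.04 and the macrophage median to between 0.11 and 0.91. The lists of acute-phase proteins (median 0.08), DNA damage repair (-0.12), cholangiocyte markers (0.16) and pancreatic acinar markers (0.13, mean -0.09) did not pass here. The adipocyte list had a positive median (0.12) with a mean of -0.27 and a downward test, and the ER-stress list a median of 0.00 and a mean of -0.03 with an upward test. The median and mean also differed in sign for immediate-early (-0.04 and 0.04, test upward), circadian (0.02 and -0.02, upward) and bile acid genes (-0.09 and 0.06, downward), none of which passed. No gene passed the adjusted p threshold in limma, while 478 of 26290 genes had an unadjusted p under 0.05, 293 higher and 185 lower, where chance alone gives about 1314.5. The slide-blocked fit had 2075, with the balance turned to 900 higher and 1175 lower. The smallest p-values among higher genes belonged to Glul, Cd274, Axin2, Rgs4 and Lect2. Rgs4, a regulator of G-protein signalling, was 4.03-fold higher. With the 2 arrays exchanged its groups overlapped, at 0.81 on the array filed as survivin-deleted liver and 0.76 in survivin-deleted HCC replicate 2. Among lower genes they belonged to Mobkl2b (now Mob3b, -1.06), Vmn1r51 (-1.88), Dntt (-2.74), Thap2 (-0.93) and XIST (without a size, since above background on 1 of 3 deleted HCC arrays). Dntt is the terminal transferase of developing lymphocytes. The groups of Mobkl2b also overlapped with the 2 arrays exchanged.

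XIST, the non-coding RNA made from the inactive X chromosome of female cells, was the only gene that passed limma within slide 2. Its main probe lay on chromosome X at 100655899 to 100655958. Its change there was -4.25 in HCC (adjusted p = 0.0301) and -4.43 in non-cancerous liver (adjusted p = 0.0234). Over its 5 probes the mean signal on slide 2 was between -2.67 and -1.76 on the 4 wild-type arrays while the 4 survivin-deleted arrays read between -7.88 and -7.18, near background. Of those 4 arrays 1 was well above background on the main probe and 0 on each of the others, so these readings and the changes just given are not exact. With readings under the detection floor raised to it, the mean over the probes still differed by -3.45. The Y-linked Eif2s3y was between 0.84 and 1.44 on the same 8 arrays. All mice are labelled male, and the sex of the marrow donors is not given in the labels. On slide 1 the mean over the XIST probes was -3.15 in wild-type liver and -6.55 in survivin-deleted HCC. It was -3.59 on the array labelled survivin-deleted liver and -5.87 on the array labelled wild-type HCC, which was above background on the main probe only. On slide 2 XIST thus parted the arrays by genotype, and on slide 1 it did so only with the 2 labels exchanged.

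**Figure D2:**
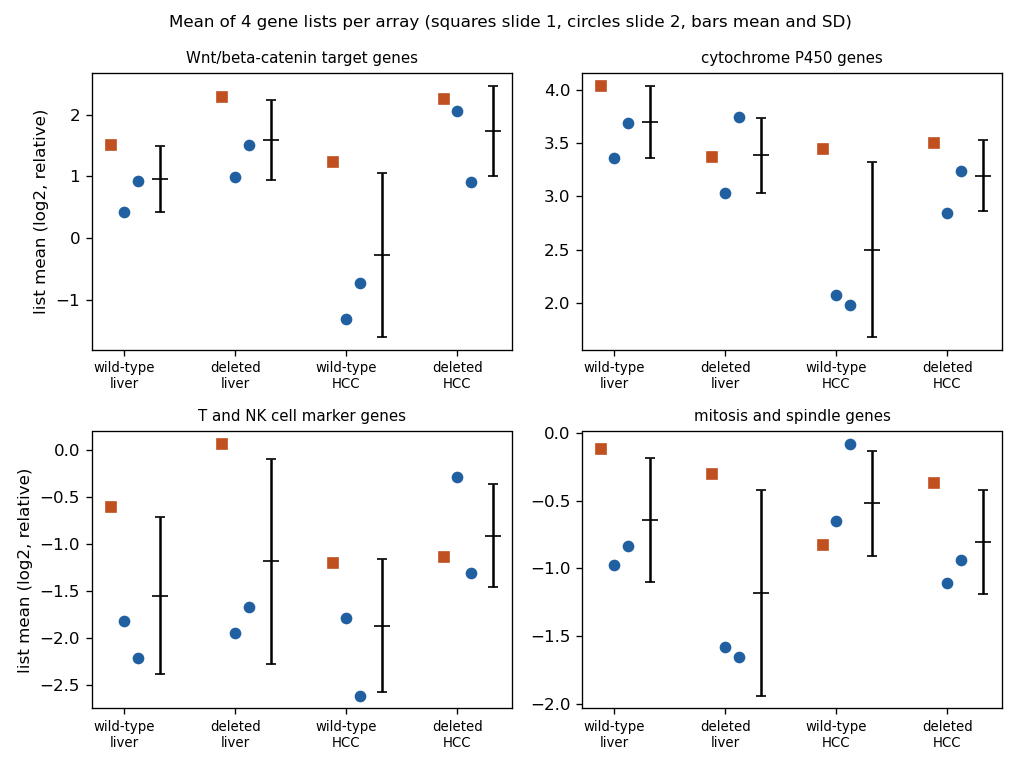
Mean of the member genes of 4 lists on each array (vertical axis, log2 signal relative to the array's 75th percentile), by group (horizontal axis), with squares for slide 1, circles for slide 2 and bars for the mean and SD of 3 arrays. Wnt target genes on slide 2 lie below 0 in wild-type HCC and above 0 in the other groups.

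In non-cancerous liver the same deletion was accompanied by lower mitotic and detoxification transcripts. Mitosis and spindle genes fell by a median of 0.61, with 27 of 30 lower (mean -0.54 ± 0.35, SE with slide as a block, 3 arrays per group). NRF2 targets, which encode antioxidant and conjugating enzymes, fell by 0.56 with 22 of 22 lower, and the glutathione transferase genes Gsta1 and Gsta4 differed by -1.44 (SE 0.60) and -0.85 (SE 0.38). DNA replication genes fell by 0.28, among them Slbp, the histone mRNA binding protein (-0.95, SE 0.25), and the ribonucleotide reductase gene Rrm2 (-0.87, SE 0.33). Erythroid markers fell by 0.80, among them Epor, the erythropoietin receptor (-1.03, SE 0.34), Car1 (-2.24, SE 0.77) and the haemoglobin chaperone gene Ahsp (-2.02, SE 0.76). The camera adjusted p-values of the mitosis, NRF2, replication and erythroid lists were 4.14e-07, 1.64e-07, 8.66e-07 and 4.77e-05, and adjusted p = 0.32, 0.31, 0.31 and 0.32 with an estimated correlation. With slide as a block they were 7.79e-07, 1.84e-07, 7.61e-07 and 0.00399. Within slide 2 the medians were -0.80, -0.69, -0.47 and -0.98. With the 2 arrays exchanged they were -0.80, -0.55, -0.47 and -0.49. The groups of Slbp then overlapped, at 1.21 on the array filed as wild-type HCC and 1.20 in wild-type liver replicate 2. The XIST levels given above parted the liver arrays of slide 2 by genotype too.

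Of the other lists in liver, secreted hepatocyte proteins fell by 0.33, with 26 of 27 lower and Serpina1a, an antitrypsin gene, at -0.67 (SE 0.24). Cholesterol synthesis genes fell by 0.35 with 22 of 22 lower, and male-biased liver genes fell by 0.50 with 17 of 17 lower. Fatty acid oxidation (median -0.28), amino acid and urea (-0.24), bile acid (-0.27), chromosomal passenger complex (-0.47), cytochrome P450 (-0.29), endothelial (-0.30), apoptosis (-0.10) and monocyte and neutrophil genes (-0.28) fell as well. The camera adjusted p-values of these 11 lists ran from 4.76e-07 to 0.0422, and adjusted p = 0.31 to 0.47 with an estimated correlation. Within slide 2 the amino acid, bile acid and P450 medians were -0.00331, -0.02 and -0.03, with adjusted p = 0.841, 0.493 and 0.576. The fatty acid oxidation (adjusted p = 0.123), endothelial (0.0627), apoptosis (0.621) and monocyte lists (0.398) did not pass there either. Wnt target genes rose by a median of 0.62, with 15 of 18 higher (adjusted p = 0.0174, and adjusted p = 0.54 with an estimated correlation). With the 2 arrays exchanged that median was 0.22 (adjusted p = 0.662). The mitosis, NRF2, replication, erythroid, secreted protein and cholesterol lists kept their call whichever array was left out, and every other list lost it without at least 1 array. The mitosis median then ran from -1.19 to -0.25 and the NRF2 median from -0.77 to -0.24. The cholesterol median ran from -0.65 to -0.12 and the replication median from -0.62 to -0.24. In all 16 of 36 lists passed, 1 up and 15 down, with 0 under an estimated correlation and 0 by fry, 18 with slide as a block, 12 within slide 2 and 17 with the arrays exchanged. The p53 list had a positive median (0.16) and the antigen presentation list too (0.05), each with a downward test that did not pass. Of the members of the called lists 0 passed over all genes by limma and 0 adjusted over the list alone, while at unadjusted p under 0.05 3 erythroid markers, 2 NRF2 targets, 2 replication genes and 1 secreted protein gene (Serpina1a) were lower.

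No single gene passed in liver by limma, and 797 had an unadjusted p under 0.05, 640 higher and 157 lower. The slide-blocked fit had 3132, 2216 higher and 916 lower. Within slide 2 the balance turned to 1459 higher and 1598 lower, and with the arrays exchanged 382 were higher and 220 lower. The smallest p-values among higher genes included those of Lynx1 (1.47), Lhb (1.59), Nhlrc4 (without a size, since above background on 1 of 3 wild-type arrays) and the pseudogene Ctsm-ps (1.28). Among lower genes they were those of the protease gene Ctse (-2.63, SE 0.67), Slbp, Serpina4-ps1 (-3.25), the steroid-metabolising Hsd17b6 (-1.73) and the proteasome inhibitor gene Psmf1 (-0.98). With the 2 arrays exchanged the groups of Slbp and Serpina4-ps1 overlapped. Across 26290 genes, which are not independent replicates, the deletion changes in HCC and in liver correlated with r = 0.343. In an exact test over 400 relabellings of the arrays within each tissue 84 gave a correlation as large (p = 0.21). These relabellings, like those for the tissue contrasts below, ignored slide. Within slide 2 r was 0.518, and with the arrays exchanged 0.289 (exact test, p = 0.29). No genes passed in either tissue, so their overlap could not be tested.

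The comparison of HCC with non-cancerous liver in wild-type mice was marked by lower drug-metabolising and antioxidant transcripts in the tumours. Cytochrome P450 genes fell by a median of 0.91, with 22 of 22 lower (mean -1.20 ± 0.33, SE with slide as a block, 3 arrays per group). Cyp1a2 differed by -3.11 (SE 0.99), Cyp3a11 by -1.10 (SE 0.39) and Cyp2c29 by -0.74 (SE 0.27). Cyp1a1 read lower too, but with no HCC array above background and 2 of 3 liver arrays no size is given. NRF2 targets fell by 0.71, again with 22 of 22 lower, led by Gsta1 (-2.84, SE 0.60, adjusted p = 0.0139 over the list alone), the quinone reductase gene Nqo1 (-1.81, SE 0.61), Gstm4 (-1.29, SE 0.42) and Ugdh (-1.12, SE 0.40). Wnt target genes fell by 1.16, with 16 of 18 lower, among them Glul (-1.17, SE 0.39), Lect2 (-1.14, SE 0.42) and the aminotransferase gene Oat (-2.74, SE 1.01). The camera adjusted p-values of these 3 lists were 5.19e-19, 7.31e-17 and 7.47e-11, and adjusted p = 0.098, 0.098 and 0.15 with an estimated correlation. With slide as a block they were 1.95e-16, 4.25e-15 and 1.25e-09, and within slide 2 the medians were -0.98, -0.80 and -1.60. Adjusted over the list alone 0, 1 and 0 members passed, and 12, 9 and 1 with slide as a block. With the arrays exchanged the medians were -0.93, -0.60 and -0.85.

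Markers of resident non-parenchymal cells were lower in wild-type HCC too. Macrophage and Kupffer cell markers fell by 0.58, with Vsig4 at -1.68 (SE 0.69) and Msr1 at -0.72 (SE 0.33). Endothelial markers fell by 0.38, with Lyve1 of sinusoidal cells at -0.69 (SE 0.31). Stellate cell and fibroblast markers fell by 0.28, with Lrat, the vitamin A storing enzyme gene of stellate cells, at -1.61 (SE 0.43, adjusted p = 0.0301 over the list alone), and the matrix genes Lum and Dcn at -1.34 (SE 0.48) and -0.98 (SE 0.41). Timp1, a metalloprotease inhibitor gene on that list, differed the other way by 2.19 (SE 0.54). Bile acid genes fell by 0.61, with the transporter gene Slco1b2 at -0.66 (SE 0.29), and monocyte and neutrophil (-0.36), female-biased (-0.54), male-biased (-0.42), amino acid and urea (-0.24), circadian (-0.26), interferon-stimulated (-0.19), S-phase (-0.19), fatty acid oxidation (-0.19) and erythroid genes (-0.18) fell too. The camera adjusted p-values of these 13 lists ran from 1.83e-08 to 0.0499, and adjusted p = 0.14 to 0.46 with an estimated correlation. The P450, NRF2, Wnt, bile acid, macrophage, monocyte, female-biased and amino acid lists kept their call whichever array was left out, with a Wnt median from -2.05 to -0.60, and every other list lost it without at least 1 array. The erythroid list lost the call with slide as a block (adjusted p = 0.101), and the stellate and S-phase lists with the arrays exchanged (adjusted p = 0.0988 and 0.104). Within slide 2 the stellate, S-phase, interferon, circadian and fatty acid oxidation lists did not pass (adjusted p = 0.0585, 0.372, 0.0986, 0.0986 and 0.0585). Mitosis and spindle genes had a median of 0.13 (adjusted p = 0.440), 0.53 within slide 2 (adjusted p = 2.02e-13) and 0.26 with the arrays exchanged (adjusted p = 0.00953). In this comparison 16 of 36 lists passed, all down, with 0 under an estimated correlation and 0 by fry, 16 with slide as a block, 19 within slide 2 and 18 with the arrays exchanged. By limma 0 genes passed and 435 had an unadjusted p under 0.05, 206 higher and 229 lower, and 1603 with slide as a block, 966 higher and 637 lower. The smallest p-values were those of Zfp462 (1.91), the NK receptor genes Klrb1a (1.68) and Klrb1b (1.39), Timp1 and Sh3bp4 (1.27) among higher genes. Among lower genes they were those of Gsta1, the sodium channel gene Scn2a1 (now Scn2a, above background on 1 of 3 HCC arrays, so without a size), Akr1c19 (-2.78), Hectd2 (-2.53) and Add3 (-1.28). With the 2 arrays exchanged the groups of Scn2a1 and Add3 overlapped.

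With survivin deleted, HCC was compared with liver in the same way. Cholesterol synthesis genes rose by a median of 0.33 with 21 of 22 higher, and mitosis and spindle genes rose by 0.37 with 28 of 30 higher (mean 0.37 ± 0.35, SE with slide as a block, 3 arrays per group). Interferon-stimulated genes rose by 0.24, with Oas2, an antiviral synthetase gene, at 1.04 (SE 0.38). Immediate-early genes rose by 0.37, with the transcription factor genes Egr2 at 1.48 (SE 0.49) and Egr1 at 0.93 (SE 0.42), and secreted senescence (0.40), ER-stress (0.25) and antigen presentation genes (0.27) rose as well. Amino acid and urea genes fell by 0.39 with 23 of 28 lower, adipocyte markers fell by 0.93 and bile acid genes fell by 0.23. Survivin-deleted liver replicate 3 carried the adipocyte difference, with a list mean of 3.29 against 0.63 and -0.51 in replicates 1 and 2, and without it the median was -0.15 (adjusted p = 0.698). Without survivin-deleted HCC replicate 2 the amino acid median was -0.06 (adjusted p = 0.691). Without 1 array or another every called list but the interferon list lost its call. The mitosis median then ran from 0.05 to 0.90 (largest adjusted p = 0.0555) and the cholesterol median from 0.10 to 0.66 (largest adjusted p = 0.0506). The cholesterol and mitosis lists both had a camera adjusted p of 9.94e-06, and adjusted p = 0.61 with an estimated correlation. The other 8 ran from 1.59e-05 to 0.0343, and adjusted p = 0.15 to 0.65 with an estimated correlation. In the slide-blocked fit the cholesterol and mitosis lists had adjusted p = 4.03e-06 and 3.15e-05, and the same 2 medians were 0.42 and 0.67 within slide 2 and 0.42 and 0.52 with the arrays exchanged. The ER-stress list did not pass within slide 2 (adjusted p = 0.439) or with the arrays exchanged (0.0661), nor did the adipocyte (0.118) and senescence lists (0.0611) within slide 2. Wnt target genes had a median of 0.05 (adjusted p = 0.111) and NRF2 targets of -0.01 (adjusted p = 0.821, test upward), and with the arrays exchanged the Wnt median was 0.45 (adjusted p = 0.00139). In total 10 of 36 lists passed, 7 up and 3 down, with 0 under an estimated correlation and 0 by fry, 10 with slide as a block, 13 within slide 2 and 15 with the arrays exchanged. No member passed over all genes or adjusted over the list alone. By limma 0 genes passed and 225 had an unadjusted p under 0.05, 87 higher and 138 lower, and 1157 with slide as a block. The smallest p-values among higher genes were those of the imprinted gene Phlda2 (1.59, SE 0.34), Fam198a (now Gask1a, 1.55), the DNA glycosylase gene Neil2 (1.08), Usp17l5 (now Usp17lc, 1.82) and Sox11 (without a size, since above background on 1 of 3 deleted liver arrays). Among lower genes Sema3d and Lypd6 were not above background on any deleted HCC array and were at least 1.34-fold and 1.97-fold lower, and Nnat, G0s2 and Id3 differed by -1.32, -1.24 and -1.14. Across genes the contrast between HCC and liver correlated with r = 0.227 between the genotypes (exact test over 400 relabellings, p = 0.38), 0.400 within slide 2 and 0.355 with the arrays exchanged (p = 0.17).

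The deletion change in HCC minus that in liver was tested as an interaction. Wnt target genes had the largest median, 1.55 with 17 of 18 members higher (camera adjusted p = 2.15e-11, and adjusted p = 0.22 with an estimated correlation). Leaving out 1 array moved this median to between 0.987 and 2.025. The same wild-type HCC arrays enter this test, the deletion change in HCC and the wild-type tissue contrast, which are not independent. Likewise the same wild-type liver arrays enter this test, the deletion change in liver and the wild-type tissue contrast. Survivin-deleted HCC lay near survivin-deleted liver (difference of list means 0.146, SE 0.44 with slide as a block). NRF2 targets (median 0.63, adjusted p = 3.29e-12) and cytochrome P450 genes (0.70, adjusted p = 1.19e-10) were also higher, each with adjusted p = 0.21 with an estimated correlation. Blocked by slide the adjusted p-values of these 3 lists were 2.23e-09, 4.87e-11 and 5.22e-09, and within slide 2 their medians were 1.72, 0.71 and 0.56. In all 21 of 36 lists passed, every one upward, with 0 under an estimated correlation and 0 by fry, 19 with slide as a block, 11 within slide 2 and 22 with the arrays exchanged. The exchange is no check of these effects, since both arrays enter the interaction with the same weight. It left every estimate as it was and changed only the spread. The Wnt list mean was 1.37 either way, with SE 0.62 as labelled and 1.00 exchanged (slide as a block). Camera compares a list with all other genes, and the median difference over all genes was -0.065. Among genes well above background on all arrays it was 0.020. By limma 0 genes passed and 146 had an unadjusted p under 0.05, and 864 with slide as a block. The smallest p-values among positive differences were those of Phlda2 (2.26, SE 0.47), Neil2 (1.97), Gsta1 (3.18), Scn2a1 and Cyp1a1. No size is given for the last 2, which were above background on 1 and 0 of 3 wild-type HCC arrays. Among negative differences they were those of the trypsinogen gene Prss1, Vmn1r52, V1ra8, Opn3 (-1.27) and Zfp462 (-1.96). Prss1 was above background on 0 of 3 arrays in wild-type liver and in survivin-deleted HCC, and Vmn1r52 and V1ra8 on 1 of 3 in wild-type liver, so their sizes are left out.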

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

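The tests of XIST, liver admixture, the share of hepatocytes and the arrays in doubt, and the counts over other splits, were chosen after seeing results.

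The deletion change differed between HCC and liver in 21 lists, each by the interaction test of camera, and each lost with an estimated correlation. With slide as a block the male-biased and apoptosis lists lost the call too (adjusted p = 0.0741 each), and only the Wnt, NRF2, P450, interferon, macrophage, monocyte and replication lists kept it whichever array was left out. The medians over genes of the difference were 1.545 for Wnt targets, 0.784 for erythroid markers, 0.703 for cytochrome P450 genes, 0.683 for macrophage markers, 0.626 for NRF2 targets and 0.557 for T and NK cell markers. They were 0.463 for monocyte and neutrophil markers, 0.453 for interferon-stimulated genes, 0.434 for male-biased genes, 0.398 for stellate cell markers, 0.384 for antigen presentation and 0.315 for female-biased genes. Replication genes had 0.300, endothelial markers 0.283, bile acid genes 0.265, mitosis genes 0.259 and hypoxia genes 0.188. Oncofetal genes had 0.179, cholesterol synthesis 0.1535, secreted hepatocyte proteins 0.132 and apoptosis regulators 0.129.

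The scanner files and the value table disagree on the array labelled survivin-deleted liver replicate 1 and the array labelled wild-type HCC replicate 1. An exchange in the scanner files would make the difference between these arrays run against the same difference on slide 2, and an exchange in the value table would make it run with it. Across genes r was -0.181 with replicate 2 and -0.00610 with replicate 3, against 0.180 and 0.0850 for the undisputed arrays, so neither could be told apart by this test. Set against wild-type liver, the array filed as survivin-deleted liver correlated with the wild-type HCC profile at 0.216 and 0.175 and with its own at 0.0441 and 0.0940, while the array filed as wild-type HCC correlated with its own at 0.137 and 0.131 and with the other at 0.131 and 0.0439. XIST was higher by 2.28 on the array filed as survivin-deleted liver (at least 1.58 at the detection floor), on 5 of 5 probes and against the order on slide 2, which fits an exchange in the scanner files, as do the Birc5 differences on slide 1, -2.35 and -1.80 only when exchanged, though these readings were chosen after the values were seen and XIST need not follow genotype on slide 1.

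Wnt target genes were higher in survivin-deleted than in wild-type HCC. Slide 2 alone, which holds neither array in doubt, gave a median of 2.55, so the rise there does not come from those arrays or slide 1. On slide 1 the list mean was 2.26 in survivin-deleted HCC. It was 1.23 on the array filed as wild-type HCC and 2.29 on the array filed as survivin-deleted liver. With the labels exchanged slide 1 thus showed no rise, and the result rested on slide 2 with 2 arrays per group. Pericentral minus periportal genes outside the fixed lists were higher by 1.42 (SE 0.46), which fits a shift from periportal to pericentral expression and describes the pattern more than it names a cause. Whether non-cancerous liver in the deleted HCC samples contributed was left open. Their mitosis list lay 0.374 (SE 0.35) above deleted liver. With the 2 arrays exchanged it lay 0.549 (SE 0.20) above, past 2 standard errors. Over both slides the list cannot decide, since it hardly parted wild-type HCC from wild-type liver. That difference was 0.123 (SE 0.35), and 0.298 (SE 0.20) with the arrays exchanged. On slide 2 alone it parted the tissues in both genotypes. List means there were -0.65 and -0.08 in wild-type HCC against -0.97 and -0.84 in wild-type liver. They were -1.11 and -0.94 in deleted HCC against -1.58 and -1.66 in deleted liver. On slide 1, as labelled, deleted HCC read -0.37 and deleted liver -0.30. A biological difference by genotype, or a difference between the tumours sampled, was not tested.

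T and NK cell markers were higher in survivin-deleted HCC, mainly on slide 2. A lower share of hepatocytes could raise every other cell type alike, and the list rose by 0.674 (SE 0.41) more than stellate markers, which cannot tell. Bone marrow donors that differed between the genotypes could also shift blood cell transcripts. XIST readings differed by -5.14 between the genotypes on slide 2, or by -3.45 with the deleted arrays raised to the detection floor, in mice labelled male with Y-linked transcripts, but the donors are not given and the difference runs with genotype, so this cannot tell either. A biological difference by genotype was not tested.

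Regrouping the arrays was used to ask how often other splits do as well. For the 4 pairwise contrasts 10 splits exist, too few for a share under 0.05. Genes past the threshold numbered 0 in each, which every one of the 10 splits equals or exceeds, so this count tests nothing. The highest other split gave 0 in HCC, 0 in liver, 1 for HCC against liver in wild type and 10 with survivin deleted. For lists the real value and highest other were 19 and 14 in HCC (1 split as large), 16 and 15 in liver (1), 16 and 17 for wild type (2) and 10 and 15 with survivin deleted (6). Of the 10 splits 4 part all same-numbered arrays as the real one does, while the others put same-numbered arrays on one side. Among the 4 the highest other list counts were 14, 15, 17 and 13, with 1, 1, 2 and 4 splits as large. The median of the Wnt list in HCC was 2.01 against a highest other of 1.28 among the 4 and 2.44 among all 10. Genes at unadjusted p under 0.05 in HCC numbered 478, against 606 among the 4 and 2625 among all 10, which points to a structure of the arrays other than the groups. For the difference between tissues the gene count of 0 is equalled or exceeded by all 100 of 100 drawn splits and tests nothing (highest other 262, again a structure of the arrays). As many lists came from 2 of 100 (real 21, highest other 21). These splits were not limited to those that part same-numbered arrays, so they mix the slides.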

How the results depend on the processing

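The exchanged and reduced fits named below were chosen after seeing results, and all other alternatives were fixed in advance. The cause was not tested for any change. With the correlation estimated, and with fry, 0 lists passed in all 5 contrasts. Genes past the threshold numbered 60, 677, 313 and 5 with array weights (deletion in HCC, deletion in liver, HCC against liver in wild type and with deletion), where slide 1 weighed 0.117 to 0.250 and slide 2 0.931 to 4.08. The 5 were 2210415F13Rik, 4930527F14Rik, Fam198a, LOC100048741 and Usp17l5. Slide 2 only gave 1 and 1 for the deletion (XIST), and the fit without both arrays in doubt 2 in HCC (Cyp3a41b, Dntt), all picked after their values were seen. Lists numbered 10 for deletion in liver with normexp and quantile scaling, 16 for HCC against liver with deletion under array weights, and for the interaction 13 with the filter on all arrays, 11 on slide 2 and 12 without both arrays in doubt. The median change over all genes was 0.051 for deletion in liver, 0.041 for wild-type HCC against liver and -0.065 for the interaction. Most lists called in these contrasts ran the other way. With the filter on all arrays these medians were -0.050, -0.019 and 0.020. The replicate block, which pairs arrays by number, left 0 genes in every contrast, gave 14, 18, 17, 10 and 19 lists and Birc5 changes of -1.077 and -0.9571.

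In the limma fit of 1 probe per gene the unadjusted p of Birc5 was 0.220 in HCC and 0.272 in liver, and it passed 0.05 in these fits. In HCC the change was -1.245 on slide 2 (p 0.0247), -1.077 with only the 2 groups (0.0207), -1.253 with array weights (0.0259), -1.617 in the value table (0.0319) and with arrays exchanged (0.0327, and 0.00462 with the slide block), and -1.613 without both arrays (0.0270). In liver it was -1.218 on slide 2 (0.0269), -1.288 with weights (0.00598), -1.505 in the value table (0.0430), -1.497 exchanged (0.0450, and 0.00720 with the slide block) and -1.586 without both (0.0289). Reversed medians were apoptosis in liver, 0.0003053 exchanged, with or without the slide block, and 0.0021 without both arrays. In the interaction they were secreted proteins -0.02949 (quantile) and -0.01111 (normexp quantile), apoptosis -0.01077 and cholesterol -0.02979 (normexp quantile), and cholesterol -0.1042 on slide 2 and without both arrays and -0.105 with weights.

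Leaving out 1 array at a time, lists numbered 11 to 19 for deletion in HCC, 11 to 18 in liver, 14 to 20 for HCC against liver in wild type, 6 to 16 with deletion and 10 to 24 for the interaction. Genes past the threshold stayed at 0 for deletion in HCC, for HCC against liver in each genotype and for the interaction. Genes at unadjusted p under 0.05 numbered 213 to 1035 for deletion in HCC, 574 to 983 in liver, 259 to 940 for HCC against liver in wild type, 108 to 664 with deletion and 101 to 279 for the interaction. Birc5 ran from -1.24 to -0.7612 in HCC and -1.958 to -0.2137 in liver, with an unadjusted limma p of 0.0136 at -1.958, without survivin-deleted liver replicate 1. Medians that crossed 0 were, in HCC, cholesterol -0.4669 to 0.002349 and senescence -0.02427 to 1.063, in liver bile acid -0.4402 to 0.03475, erythroid -0.585 to 0.0005622 for wild-type HCC against liver and immediate-early -0.005518 to 0.6496 with deletion. For the interaction they were apoptosis -0.007257 to 0.2209, cholesterol -0.2167 to 0.314, female-biased -0.01283 to 0.8089, male-biased -0.1394 to 1.274, stellate -0.188 to 0.5212 and mitosis -0.02799 to 0.7881. Bile acid in liver crossed 0 without wild-type liver replicate 1, which had 49.0% of spots well above background. Without the same array apoptosis, cholesterol, female-biased and mitosis crossed 0 in the interaction. Cholesterol also did so without survivin-deleted HCC replicate 1 or survivin-deleted liver replicate 3.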

Other observations

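The tests in this part were chosen after seeing results, except that the zonation lists and their test were written before their values were seen.

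Genes that mark the zones of the liver lobule moved with the Wnt targets in survivin-deleted HCC. All 12 measured pericentral genes outside the fixed lists were higher (median 0.68), with Lhpp, a phosphatase gene, at 3.19 and the cation transporter gene Slc22a3 at 2.41. Of 13 periportal genes 10 were lower (median -0.42), with Hsd17b13 of lipid droplets at -1.23. The difference of the list means was 1.42 (SE 0.46), 1.96 (SE 0.57) on slide 2 and 1.26 (SE 0.56) with the arrays exchanged. In non-cancerous liver it was 0.62 (SE 0.46).

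The Y-linked genes were read beside XIST. Eif2s3y was well above background on all 12 arrays. Ddx3y was so too, but at -1.08 in wild-type liver replicate 3 and -5.00 in wild-type HCC replicate 3, where the other arrays of slide 2 lay between 0.67 and 2.10. Neither pattern was tested.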
